A study of Mus musculus with 17 samples.

How the data were processed

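RNA bound to ribosomes was sequenced from the corpus callosum, the white matter tract between the hemispheres, of male mice. The mice carried the RiboTag allele, an HA-tagged ribosomal protein Rpl22 that is switched on by Cre recombinase, here under GFAP-Cre, which targets astrocytes. No library of total RNA was used here, so enrichment was not tested, and transcripts of other cell types were abundant. Mice ate chow with 0.2% cuprizone, a copper chelator that kills oligodendrocytes and strips myelin, for 5 weeks and then returned to normal chow. Age-matched mock mice are the controls. Samples were taken at 5 weeks (acute demyelination), 5.5 weeks (early remyelination) and 7 weeks (late remyelination). Per the labels there are 17 libraries in 6 groups, with 3 libraries per group except 2 in the 5-week mock group. The 5-week libraries form batch 1 and the others batch 2, so differences between the 5-week and later comparisons cannot be separated from the batch.

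The deposited values are counts per Ensembl gene for 9 libraries. Per the submitters' processing notes they come from FastQC 0.11.9, STAR 2.5.4b and featureCounts 1.6.0, with no normalization. The notes name the genome builds GRCm38/mm10 and GRCm39/mm39 without saying which was used for which library, so no gene coordinates are given. Batch 1 lists 55471 gene identifiers and batch 2 lists 55414, of which 52373 are in both. Gene symbols came from GENCODE release M21, which names 99.4% of the batch 1 and 94.0% of the batch 2 identifiers. The strand setting of the counting is not stated in the sources used here, so reads from overlapping genes and close paralogs may be shared between names.

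The deposited columns of the other 8 libraries are also whole numbers, with no stated unit, but they do not behave as separate read counts. Among genes with 500 or more counts, between 46.6% and 96.2% of the values in each of these columns equal another library of its group plus an integer from 1 to 10. They are not independent read counts and were not used as samples. The library that each of them repeats was used as 1 sample. This left 3 cuprizone and 2 mock libraries at 5.5 weeks (mock replicates 1 and 3), and 1 library per group at 5 weeks (cuprizone 1, mock 2) and at 7 weeks (cuprizone 2, mock 3). The mean of such libraries would carry the added integers, so the base library was used alone and the mean was run as an alternative. A fit of all 17 libraries had been planned before the data were examined. It is given only as an alternative, because libraries that repeat one another carry no spread between mice.

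At 5.5 weeks, genes passing edgeR's filterByExpr (minimum count 10) were scaled by TMM and tested with edgeR's quasi-likelihood F test with robust dispersion, two-sided, with Benjamini-Hochberg adjustment over all genes tested and a threshold of 0.05. The residual degrees of freedom were 3 and the median prior degrees of freedom 8.6. The p-values measure spread between these libraries, which the labels call biological replicates. Levels are CPM, counts scaled to a common library size by TMM, given as mean ± SD. On simulated data of this design with 200 changed genes, the test called 41.8% of genes changed 1.5-fold, 89.6% of genes changed 2-fold and 100% of genes changed 4-fold, with 6 false calls among 15819 genes tested. The changed genes were drawn only from genes above a minimum mean count. Each gene was given the spread of the fitted trend at its level, with no further difference between genes. These rates therefore do not describe genes of low count or of unusual spread.

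At 5 and 7 weeks, 1 library per group gives no measure of spread, so no p-value is given. A fit of the 9 libraries together borrows the spread of the 5.5-week groups for these lone libraries and is given as an alternative. Genes with a CPM of at least 5 in at least 1 of the 2 libraries were compared by the log2 ratio of TMM-scaled CPM with a prior count of 2, and genes that differed by at least 2-fold were counted. A gene low in 1 library is therefore measured only if it is high in the other. This favours large ratios among genes and lists of low level. Ratios of counts carry exact (Clopper-Pearson) 95% intervals. Where the mock count was 0, the fold is a lower bound against a floor of 3 counts in that library. Reads are not independent molecules, so these intervals and bounds cover counting error only and not differences between mice. The choice of libraries, the CPM minimum and the 2-fold measure were made after the data were examined.

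Before the data were examined, 24 functional gene lists and 12 lists of cell type markers were fixed. At 5.5 weeks, lists with 5 or more tested genes were tested with limma's camera on the edgeR model, with a preset inter-gene correlation of 0.01, and adjusted over the lists of this 1 contrast, since the other planned contrasts have no replicates. camera with an estimated correlation and fry, directional and mixed, were run beside it. Unless another test is named, a list described as called or not called refers to camera with the preset correlation. That test looks for a shift in 1 direction. Mixed fry also counts members that move in opposite directions, and its results are given for the main fit only. Counts of members are given at the threshold over all genes tested and, for the same genes, adjusted over the list alone. At 5 and 7 weeks each list's median was ranked among 10000 random lists matched in expression over 20 bins. This percentile describes position among genes of 1 pair of libraries and is not a test. None of the 67 list medians moved when genes with a count of 0 were set at the floor.

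At 5.5 weeks the genes named in the text follow a rule fixed before the data were examined. It takes the 8 called genes with the largest positive and the 8 with the largest negative log2 fold change. These need an average log2 CPM of at least 3, a proper symbol and no overlap between cuprizone and mock libraries. The rule adds a fixed set of marker genes and the called members of each list with the lowest p. It was planned for 5 and 7 weeks too, where no p-value is available. There it was replaced, after the data were examined, by ranking by size alone, also for list members. The average log2 CPM, the proper symbol and the fixed marker genes were kept. Malat1, Cx3cr1, Eno1, Tyrobp at 7 weeks and genes whose direction at 5.5 weeks was the opposite of that at another time were chosen after their values were seen. The gene families were chosen after the data were examined but before their medians were computed.

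The alternatives were RLE size factors, DESeq2, limma-voom with sample weights, no filter on low counts, a filter of 1 CPM in 5 libraries, a replicate block, each library left out in turn, and all deposited libraries. Added after the data were examined were a fit of the 9 libraries together, means of repeated libraries, and protein-coding genes alone. The software was R 4.3.3 with edgeR 4.0.16, limma 3.58.1 and DESeq2 1.42.0, and Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.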

Results

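Ribosome-bound RNA of GFAP-Cre RiboTag mice was measured in 17 corpus callosum libraries, 3 per group except 2 in the 5-week mock group. Total counts per library ranged from 20797535 to 30400048 in the 9 libraries used. Among those 9, between 19496 and 34576 genes had a count. The highest number was in the 7-week cuprizone library, and the other 8 had at most 23980.

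In 8 of the 17 libraries a large share of the values repeat another library of the group. Among genes with 500 or more counts, the share lying 1 to 10 counts above the other library ranged from 46.6% in 5-week mock 1 to 96.2% in 5.5-week mock 2. Of the 136 pairs of libraries, 11 had over 40% of these genes within 10 counts of each other, all within a group, and in the other pairs the share was at most 4.26%. Random sampling of reads would give at most 15.6%. The 5.5-week comparison therefore rests on 3 cuprizone and 2 mock libraries, and the 5-week and 7-week comparisons on 1 library per group without replicates.

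The 5.5-week comparison asks how astrocyte translation differs from mock when remyelination begins. Gfap, the astrocyte intermediate filament (ENSMUSG00000020932, chromosome 11), rose from 1146 ± 43.5 CPM (SD, n = 2) in mock to 5425 ± 577 CPM (SD, n = 3) after cuprizone, a log2 fold change of 2.24 ± 0.13 (SE; edgeR adjusted p = 8.59e-06). Vim, another intermediate filament, rose by 1.82 ± 0.17 on the log2 scale (edgeR adjusted p = 0.00021). The protease inhibitor A2m rose from 0.911 ± 0.133 to 13.4 ± 0.959 CPM, and complement component C4b from 15.9 ± 0.411 to 90.5 ± 7.77 CPM (edgeR adjusted p = 5.07e-06 for both). Serping1, the C1 inhibitor, rose 7.71-fold, S1pr3, a sphingosine phosphate receptor, 5.17-fold, and the interferon-induced GTPase Gbp2 4.95-fold. Ttr, the transthyretin made by choroid plexus, rose from 1.39 ± 0.245 to 20.8 ± 11.5 CPM (edgeR adjusted p = 0.00694), with values of 9.46, 20.7 and 32.4 CPM in the 3 cuprizone libraries. Among genes that fell, Ptgds, prostaglandin D synthase, went from 297 ± 7.80 to 118 ± 19.3 CPM (log2 fold change −1.33 ± 0.13, edgeR adjusted p = 0.000364). Rasgrp3 fell by 1.23, Agt (angiotensinogen) by 1.25, the oligodendrocyte gene Anln by 1.09, Serpinb1a by 0.98, D7Ertd443e by 0.90, the thyroid hormone transporter Slco1c1 by 0.85 and the glycogen phosphorylase Pygm by 0.85 on the log2 scale. Of 16086 genes tested, 173 rose and 63 fell, 117 and 25 of them by at least 2-fold. In all 236 the 3 cuprizone libraries lay on 1 side of both mock libraries. Chance gives this arrangement to 20% of genes that were not picked. These 236 were picked by their difference in the same libraries, so the arrangement adds no support. The counts depend on single libraries: without mock 1 they were 57 and 31, without mock 3 they were 49 and 16, without cuprizone 1 they were 113 and 17, and without cuprizone 3, 155 and 24. Of the genes named in this paragraph, Ttr lost its call without mock 1, mock 3 or cuprizone 2, Agt without any 1 library other than mock 3, Anln without mock 3 or cuprizone 1, Serpinb1a without either mock library, D7Ertd443e without any 1 library other than cuprizone 2, and Slco1c1 without mock 1. Ttr also lost its call with no filter on low counts, in the fit of 9 libraries and with all 17, Agt with the filter of 1 CPM in 5 libraries, in the fit of 9 libraries and with the 6 or 17 libraries as deposited, D7Ertd443e with that filter, the mean of mock 1 and 2 and the 6 or 17 libraries, and Anln with all 17.

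Many genes of the reactive astrocyte lists rose at 5.5 weeks. In the pan-reactive list 11 of 13 members rose and 12 did when adjusted over the list alone, with a median log2 fold change of 2.02 (camera adjusted p = 5.65e-71, and adjusted p = 0.0314 with an estimated correlation). Serpina3n, a serine protease inhibitor, went from 31.4 ± 3.04 to 89.6 ± 5.47 CPM, and Cd44, a hyaluronan receptor, rose by 1.61 on the log2 scale but lost its call without mock 3. Timp1 reached 1.03 CPM and Steap4 1.00 CPM on average from 0.0186 CPM each, and both lost their calls without either mock library. Steap4 also lost it with the 6 libraries as deposited and with the mean of mock 1 and 2. Lcn2, the iron-carrying lipocalin, averaged 0.591 against 0.0557 CPM and was not called (edgeR adjusted p = 0.0815). In the A1-type list, genes first described after inflammatory stimulation, 8 of 12 rose and 9 did when adjusted over the list alone (median 1.42, camera adjusted p = 3.51e-34, and adjusted p = 0.0314 with an estimated correlation). With any 1 library left out, both of these lists lost the call made with an estimated correlation (adjusted p from 0.0904 to 0.246), as they did with a replicate block (adjusted p = 0.493) and in a fit of the 9 libraries (adjusted p = 0.0976). The A1-type genes include C3, which rose by 1.94 on the log2 scale (edgeR adjusted p = 0.0195, lost without mock 1, mock 3 or cuprizone 1). In the A2-type list, genes first described after ischemia, 4 of 11 rose and 8 did when adjusted over the list alone (median 0.68, camera adjusted p = 3.15e-16, but adjusted p = 0.056 with an estimated correlation). Tgm1, a transglutaminase, averaged 4.04 ± 1.10 CPM against 0.0557 CPM in mock, and Cd109 rose by 2.16 on the log2 scale but lost its call without mock 3. Of 26 homeostatic astrocyte genes, Slc7a10, an amino acid transporter, fell by 0.57 (edgeR adjusted p = 0.0455, lost without any 1 library other than cuprizone 2 and with the filter of 1 CPM in 5 libraries) and 25 were not called, while 7 fell when adjusted over the list alone (median −0.21, camera adjusted p = 1.42e-06, adjusted p = 0.532 with an estimated correlation). The water channel Aqp4 was at −0.10, the glutamate transporter Slc1a2 at −0.02, Aldh1l1 at −0.15 and the tagged protein's gene Rpl22 at 0.01.

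Some genes of complement, interferon response and antigen presentation rose at 5.5 weeks. In the complement list 4 of 11 members rose and 5 did when adjusted over the list alone, C4b and Serping1 among them (median 0.67, camera adjusted p = 1.04e-17, and adjusted p = 0.0314 with an estimated correlation). With any 1 library left out that last p was 0.107 to 0.246, with a replicate block 0.493 and in a fit of the 9 libraries 0.0976, so the call was lost each time. In the interferon response list 9 of 25 rose and 21 did when adjusted over the list alone (median 0.83, camera adjusted p = 4.63e-28, but adjusted p = 0.113 with an estimated correlation). The antiviral genes Ifitm3 and Oasl2 rose by 1.16 and 1.29 on the log2 scale. In the antigen presentation list 5 of 17 rose and 11 did when adjusted over the list alone (median 0.76, camera adjusted p = 1.28e-13, but adjusted p = 0.079 with an estimated correlation). The immunoproteasome subunit Psmb8 rose by 1.40 (lost without mock 1) and the MHC class I gene H2-D1 by 0.82 (lost without either mock library). Of 23 immediate early genes 3 rose, 4 when adjusted over the list alone (median 0.23, camera adjusted p = 2.2e-06, but adjusted p = 0.079 with an estimated correlation). Fos rose by 0.90 (lost without mock 1) and Atf3 by 2.47 (lost without mock 3) on the log2 scale. In the extracellular matrix list 5 of 28 rose and 8 did when adjusted over the list alone. Its median was −0.05 while camera placed it higher (adjusted p = 0.0086, but adjusted p = 0.581 with an estimated correlation), a call lost without mock 3 (adjusted p = 0.475) or cuprizone 2 (adjusted p = 0.148) and in a fit of the 9 libraries (adjusted p = 0.123). Of 12 chemokines and cytokines, Cxcl10 rose by 1.64 (lost without mock 1, mock 3 or cuprizone 1). Il33 fell by 0.77 (lost without mock 3, cuprizone 1 or cuprizone 3 and with the 6 libraries as deposited). The list was not called by camera (camera adjusted p = 0.455) but was by mixed fry (mixed fry adjusted p = 0.0234).

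Few single genes of lipid and energy metabolism were called at 5.5 weeks. In cholesterol synthesis 3 of 27 genes fell, while 9 fell and 1 rose when adjusted over the list alone (median −0.20, camera adjusted p = 6.97e-08, but adjusted p = 0.056 with an estimated correlation). Fdft1, squalene synthase, went from 174 ± 13.9 to 112 ± 8.72 CPM (lost without mock 3, cuprizone 1 or cuprizone 3), and Msmo1, a sterol oxidase, from 164 ± 7.05 to 111 ± 7.17 CPM (lost without any 1 library other than cuprizone 2). Among 28 genes of cholesterol efflux and lipid transport 2 rose, and 4 rose and 2 fell when adjusted over the list alone (median 0.06, camera adjusted p = 0.0231, lost without mock 3 at 0.377 or cuprizone 2 at 0.111, and adjusted p = 0.581 with an estimated correlation). Abca1, the cholesterol exporter, rose by 1.04 on the log2 scale (lost without mock 3), and Apod by 0.87 (lost without either mock library and with the filter of 1 CPM in 5 libraries). None of the 59 nuclear-encoded respiratory chain genes was called by edgeR over all genes (38 at an unadjusted p under 0.05, 1 called by DESeq2, 0 by limma-voom), and 31 fell when adjusted over the list alone (median −0.28, camera adjusted p = 8.06e-21, but adjusted p = 0.281 with an estimated correlation). The 46 ribosomal protein genes (median −0.19, camera adjusted p = 4.6e-07) and the 33 lysosome genes (median 0.13, camera adjusted p = 0.00168, lost without mock 3 at 0.231) had an adjusted p = 0.581 each with an estimated correlation. Neither held a gene called by edgeR, DESeq2 or limma-voom, with 7 and 6 genes at an unadjusted edgeR p under 0.05. In the integrated stress response list 3 of 36 rose, among them Nupr1 by 1.27 (lost without mock 1), and the list was not called (median 0.01, adjusted p = 0.31). The lists for the unfolded protein response, NRF2 targets, copper handling, glycolysis, growth factors, phagocytosis, cell cycle and the mitochondrial genome were not called (camera adjusted p from 0.126 to 0.866). Mixed fry called phagocytosis, the integrated stress response and NRF2 targets (mixed fry adjusted p = 0.00029, 0.000857 and 0.00264). It also called growth factors, glycolysis and copper handling (mixed fry adjusted p = 0.0112, 0.013 and 0.0403). The unfolded protein response, cell cycle and mitochondrial genome were not called by it either (mixed fry adjusted p from 0.181 to 0.7).

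Markers of other cell types were present in the immunoprecipitate at 5.5 weeks and some moved with cuprizone beside the groups above. Of 22 mature oligodendrocyte markers 5 rose and 2 fell, and 9 rose and 4 fell when adjusted over the list alone (median 0.25, camera adjusted p = 0.00186, lost without mock 1 at 0.173 or cuprizone 2 at 0.213, and adjusted p = 0.581 with an estimated correlation). The myelin gene Mog went from 267 ± 27.7 to 459 ± 74.7 CPM (lost without either mock library), while Aspa fell by 0.80 on the log2 scale (lost without mock 3 or cuprizone 1). Mbp was at 0.48 and was not called (edgeR adjusted p = 0.13). Gpr17, a marker of newly formed oligodendrocytes, rose from 34.2 ± 2.83 to 65.7 ± 8.69 CPM (lost without mock 3) and was the only called member of 17 precursor markers, of which 7 rose when adjusted over the list alone (median 0.29, camera adjusted p = 2.75e-06, but adjusted p = 0.388 with an estimated correlation). None of 21 microglial markers was called by edgeR over all genes (9 at an unadjusted p under 0.05, 3 called by DESeq2, 0 by limma-voom), and 5 rose when adjusted over the list alone (median 0.70, camera adjusted p = 2.75e-06, but adjusted p = 0.532 with an estimated correlation). Of 14 markers of disease-associated microglia 5 rose and 9 did when adjusted over the list alone, Lyz2 by 2.84 on the log2 scale among them (median 0.67, camera adjusted p = 7.71e-15, but adjusted p = 0.0807 with an estimated correlation). The choroid plexus list (1 of 7 rose, Ttr, and 2 when adjusted over the list alone) had a median of 0.65 (camera adjusted p = 1.41e-06, but adjusted p = 0.079 with an estimated correlation). The fibroblast list (1 of 8 fell, Ptgds, and 2 when adjusted over the list alone) had a median of −0.44 (camera adjusted p = 0.00085, lost without mock 1 at 0.097, in a fit of the 9 libraries at 0.0621 and with all 17 at 0.0661, and adjusted p = 0.115 with an estimated correlation). Neuronal, endothelial, pericyte, ependymal and neural stem cell lists were not called (camera adjusted p from 0.539 to 0.734), and the lymphocyte list had 3 tested genes, too few for a test. Mixed fry called the ependymal and neural stem cell lists (mixed fry adjusted p = 0.0435 and 0.00897). It did not call the neuronal, endothelial and pericyte lists (mixed fry adjusted p from 0.337 to 0.757). The synaptic gene Snap25 was among the abundant transcripts, with 4786 CPM after cuprizone and 5073 CPM in mock.

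**Figure D1:**
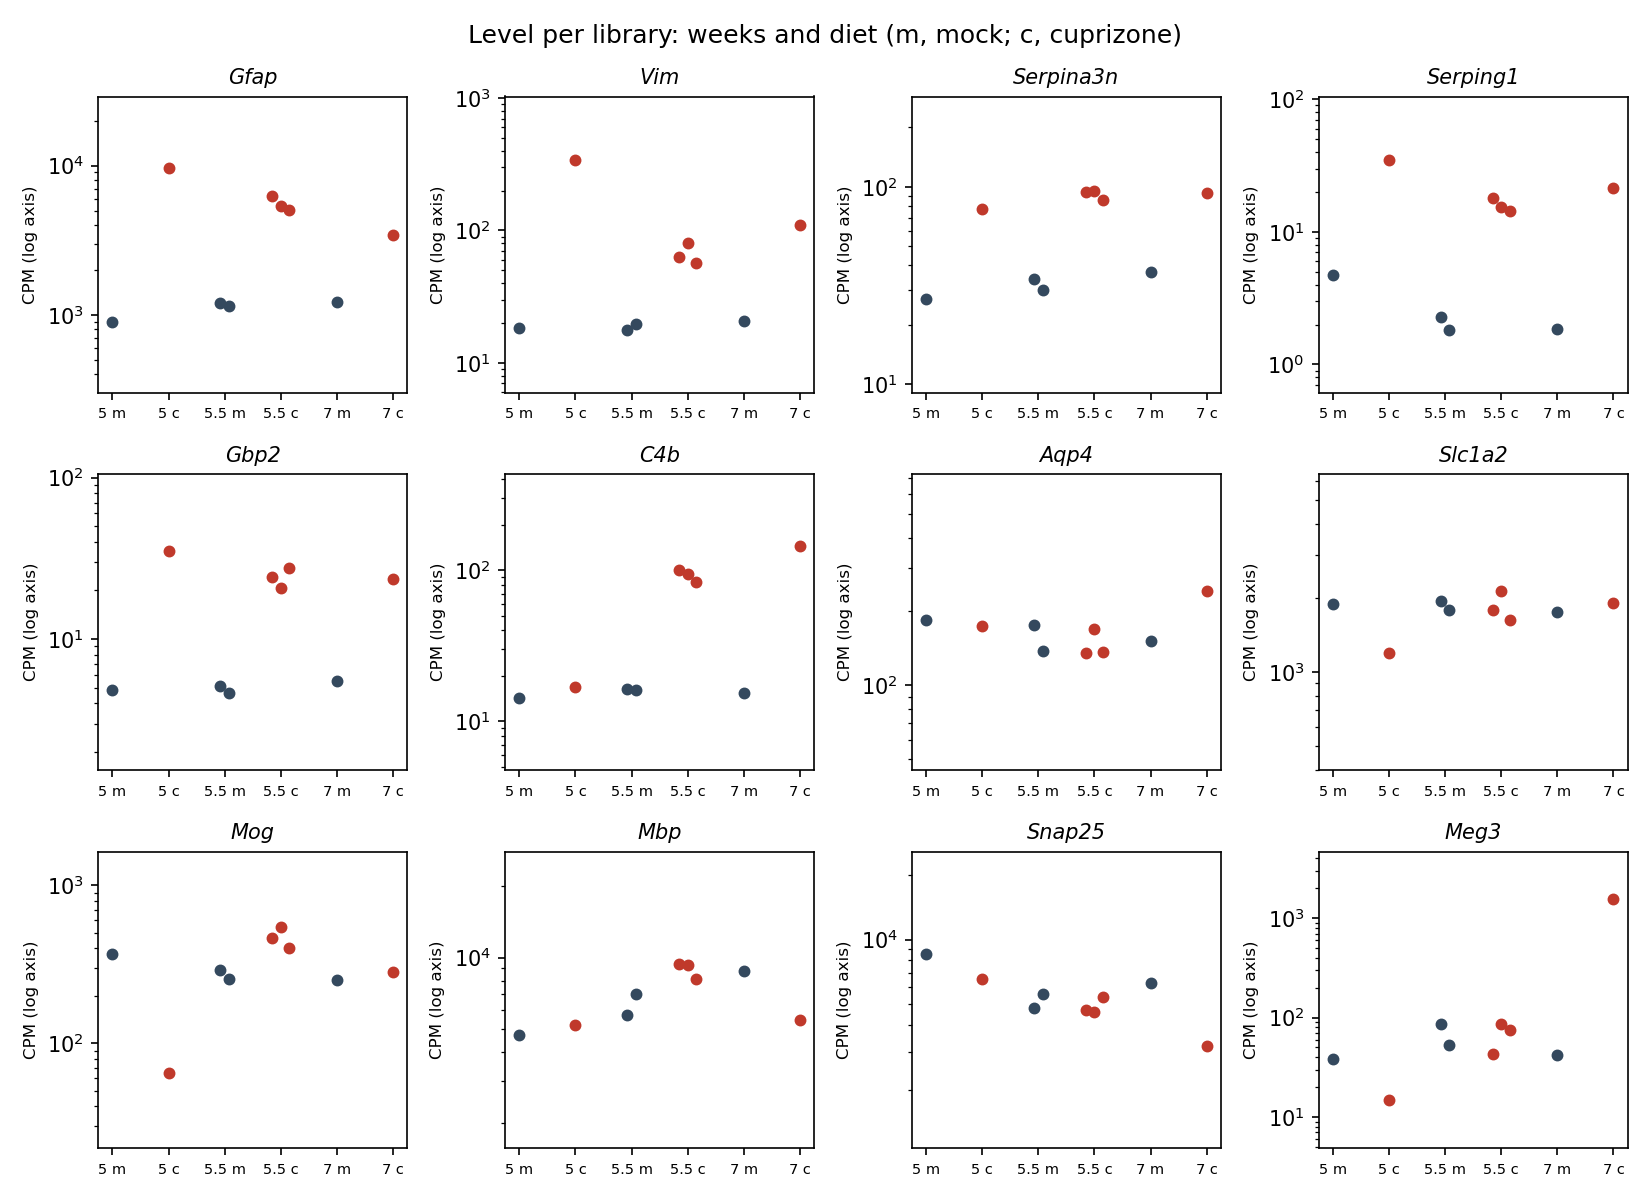
CPM (log axis) of selected genes in each of the 9 libraries used, by time point and group, where each point is 1 library. With TMM scaling over the libraries of a batch, Gfap lay between 5063 and 6289 CPM in the 3 cuprizone libraries at 5.5 weeks and at 1197 and 1146 CPM in the mock libraries.

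The 5-week comparison describes astrocyte translation at acute demyelination, in 1 library per group. Vim was 18.6-fold higher in the cuprizone library (95% interval 16.7 to 20.7; 342 against 18.4 CPM) and Gfap 10.8-fold higher (10.6 to 10.9; 9691 against 900.2 CPM). The stress-response gene Nupr1 was 10.6-fold and the transcription factor Atf5 8.68-fold higher. Hspb6, a small heat shock protein, Serping1 and Gbp2 had log2 ratios of 2.87, 2.86 and 2.84. Eno1b, a near-copy of Eno1, had 2.82 while Eno1 had −0.51, so reads shared between the copies leave its value uncertain. With no count in mock, Tgm1 was at least 205-fold, Ggta1 at least 123-fold, Lcn2 at least 68.6-fold, Spp1 at least 67.4-fold, Lyz2 at least 47-fold and Atf3 at least 38.8-fold higher. Lower in the cuprizone library were Ptgds (51.7-fold, 45.3 to 59.1), the myelin gene Mal (20.3-fold, 18.7 to 21.9) and the adhesion gene Cntn2 (17.2-fold, 13.6 to 22.1). Anln, Serinc3, Ppp1r14a, Msmo1 and Ttr had log2 ratios of −3.32, −3.31, −3.23, −3.07 and −3.06. Of 11570 genes, 1029 were at least 2-fold higher and 1409 at least 2-fold lower. Between libraries of 1 group at 5.5 weeks, 7 to 54 genes differed 2-fold, and the difference between mice at 5 weeks is unknown.

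By list at 5 weeks, the pan-reactive median was 2.33 (7 of 9 measured genes at least 2-fold higher, above 100% of matched random lists) and the A1-type median 1.15 (4 of 8 higher, 2 lower). Of 7 measured A2-type genes 6 were at least 2-fold higher and none lower. Homeostatic astrocyte genes had a median of −0.62 (1 of 26 higher, 6 lower). Stress genes differed by list. Among integrated stress response and ATF4 targets 15 of 33 were higher and 1 lower (median 0.80), with the pseudokinase Trib3 34.5-fold higher (22.4 to 56.0). NRF2 targets were at 0.21 (7 of 29 higher), with Hmox1 at 2.39 and Nqo1 at 1.80, while the unfolded protein response was at −1.06 (11 of 20 lower). Cholesterol synthesis was at −1.20, with 15 of 25 lower, among them Msmo1, 8.41-fold lower (7.79 to 9.08; 35.1 against 294.8 CPM). Lysosome genes were at −1.19 (18 of 32 lower), phagocytosis genes at −0.89 and mitochondrial-genome genes at −1.89 (7 of 7 lower). Mitochondrial mRNA was at 107.5 CPM in the cuprizone library against 383.3 CPM in mock, and no other library lay under 311.1 CPM. Malat1 was at 57.6 against 120.7 CPM and Meg3 at 14.65 against 38.67 CPM, while Cx3cr1 was at 8.18 against 3.27 CPM. Whether this cuprizone library held less RNA from outside the tagged ribosomes was not tested. Interferon genes were at 0.58 (6 of 21 higher, 2 lower), antigen presentation genes at −0.52 (3 of 11 higher, 3 lower) and cell cycle genes at 1.06 (10 of 19 higher, 1 lower). Beside these groups, mature oligodendrocyte markers were at −1.72 (16 of 22 lower), precursor markers at 0.66 (6 of 16 higher, 2 lower), microglial markers at 1.89 (10 of 11 higher, with Tyrobp at 3.45 and C1qc at 2.34), disease-associated microglial markers at −0.12 (4 of 10 higher, 2 lower), ependymal markers at 1.36, neural stem cell markers at 1.02 and neuronal markers at −0.40. Only 11 of 24 listed microglial markers were measured, since those low in mock entered only if high in the cuprizone library. The share of 10 of 11 is raised by this. Shares of the pan-reactive, A1-type, A2-type and cell cycle lists are raised in the same way. Lcn2, Ggta1, Tgm1, Tm4sf1 and Ube2c were under 5 CPM in mock and entered only through the cuprizone library. Trem2, at 4.045 CPM after cuprizone and 4.047 CPM in mock, was not measured. Mbp was at 0.15. The 572 measured members of gene families that encode membrane and secreted proteins had a median of −0.88, and 618 members of cytosolic and nuclear families had 0.11. Random lists were matched in expression only. Whether the lower lysosome, phagocytosis, unfolded protein response and cholesterol synthesis medians go beyond this wider pattern was therefore not tested.

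The 7-week comparison describes late remyelination, again in 1 library per group. Lyz2, the lysozyme of myeloid cells, was 107.7-fold higher in the cuprizone library (72.2 to 168.4) and the MHC class II invariant chain Cd74 87.2-fold higher (57.4 to 139.4). Vtn had a log2 ratio of 5.69, the noncoding RNAs Kcnq1ot1 and Meg3 had 5.47 and 5.13, Snhg11, which the annotation used lists as protein-coding, had 4.94, and the myeloid genes Trem2 and Mpeg1 had 4.88 and 4.87. Gfap and Vim were 2.62-fold (2.59 to 2.65) and 4.96-fold (4.54 to 5.42) higher, C4b 8.84-fold (8.01 to 9.77), and Serpina3n, A2m and C3 had log2 ratios of 1.23, 4.54 and 4.84. Aqp4 was at 0.58. Lower in the cuprizone library were the activity-induced gene Arc (8.95-fold, 8.57 to 9.35; 80.1 against 716.5 CPM), Rasd1, Spink8, Lefty1, Dusp4, Nr4a1, Fibcd1 and Rgs14, with log2 ratios from −2.97 for Rasd1 to −2.26 for Rgs14. The lone mock library was itself high in these genes, with CPM scaled over the libraries of a batch. Arc was at 654.1 CPM in it, against 194.7 and 147.9 CPM in the 5.5-week mock libraries. In the 7-week cuprizone library it was at 77.6 CPM. For Nr4a1 these values were 303.5, 86.5, 96.7 and 60.15 CPM. How much of these ratios belongs to the mock library cannot be told. Mbp was at −0.78 and Snap25 at −1.05. Snap25 was the only 1 of 20 neuronal markers that was at least 2-fold lower. At least 2-fold higher were 6, with Sst at 3.40. Of these, Slc32a1 and Reln were under 5 CPM in mock and entered only through the cuprizone library. The neuronal median was −0.35, above 92.7% of matched random lists. Of 12173 genes, 1205 were at least 2-fold higher and 674 at least 2-fold lower, and the median of all was −0.23.

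By list at 7 weeks, the pan-reactive median was 2.31 (8 of 9 higher), the A1-type median 1.71 (9 of 12 higher), the interferon median 0.66 (7 of 22 higher), the antigen presentation median 1.44 (9 of 14 higher) and the complement median 3.71 (6 of 6 higher). The complement list had 6 of 14 listed members measured. C3, C3ar1 and Serping1 were under 5 CPM in mock and entered only through the cuprizone library, which raises the share. The same holds for Osmr and Cd44 in the pan-reactive list and Ggta1 and Srgn in the A1-type list. It holds below for Trem2 and Ptprc among microglial markers and Cldn5 and Tek among endothelial markers. Among pericyte markers it holds for Vtn and Abcc9. Extracellular matrix genes were at 0.79 (11 of 24 higher). Respiratory chain genes were at −0.92 (20 of 59 lower), immediate early genes at −0.92 (10 of 21 lower), ribosomal protein genes at −0.59, oligodendrocyte markers at −0.44 (5 of 22 lower), cholesterol synthesis at −0.44 and the integrated stress response at −0.39. With the median of all genes below 0, the oligodendrocyte median lay above 85.0% of matched random lists, that of cholesterol synthesis above 26.9% and that of the integrated stress response above 20.8%. The immediate early median rests on a mock library in which Arc, Nr4a1, Fos and Egr2 lay above both 5.5-week mock libraries. Beside these groups, microglial markers had a median of 4.21 (22 of 22 higher, Tyrobp at 4.37), disease-associated microglial markers 3.00 (8 of 14 higher), endothelial markers 5.59 (14 of 15 higher), pericyte markers 3.55 (10 of 10 higher) and mitochondrial-genome genes 2.88 (6 of 7 higher). The antigen presentation list was led by Cd74 and H2-Aa, at 6.33 and 5.49, and the complement list by C3ar1 and C3, at 6.24 and 4.84. With microglial and vascular markers this high, the reactive and immune list medians cannot be assigned to astrocytes. The same holds for Vim, C4b, A2m and C3. The 7-week cuprizone library stood apart from the other 8 in level, with CPM scaled over the libraries of a batch. Malat1, a nuclear noncoding RNA, was at 3260 CPM against 57.6 to 167.9, the microglial Cx3cr1 at 97.3 against 2.48 to 8.18 and the endothelial Cldn5 at 56.3 against 0.093 to 0.975 CPM. With protein-coding genes alone, 1053 were at least 2-fold higher and 643 lower.

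**Figure D2:**
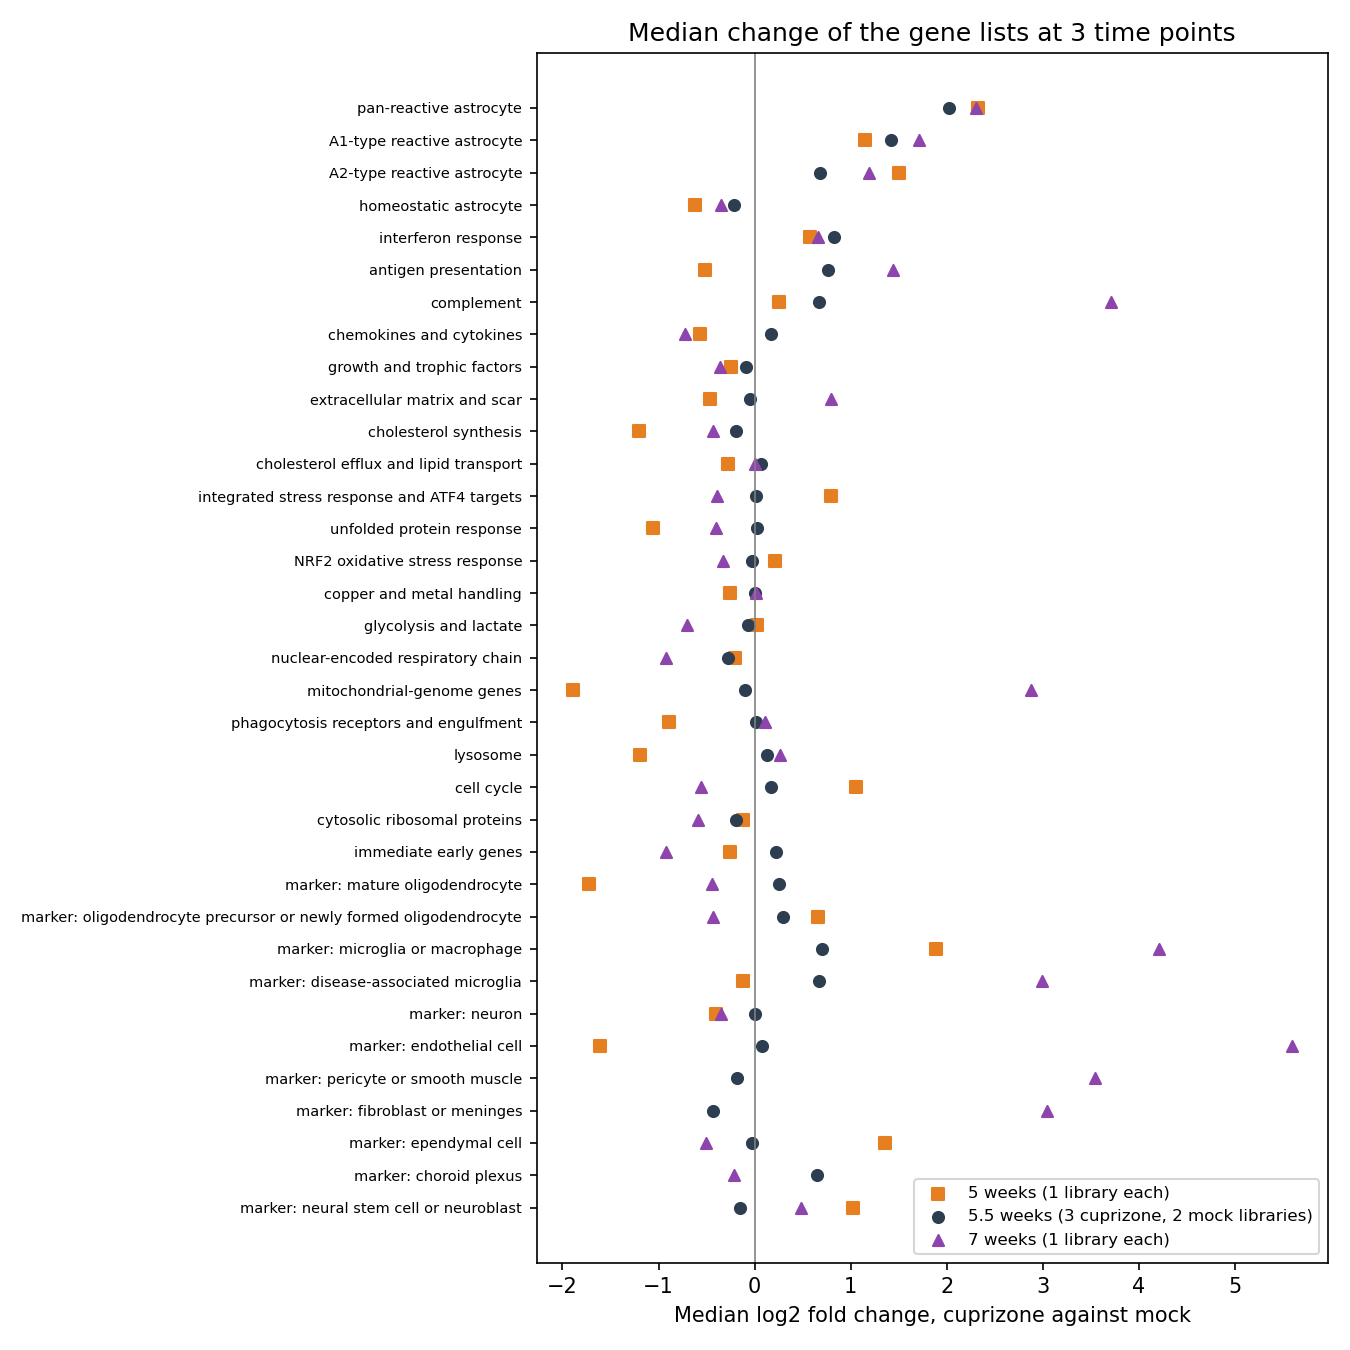
Median log2 fold change of cuprizone against mock for 35 gene lists at 5, 5.5 and 7 weeks, without a point where fewer than 3 genes were measured. The pan-reactive list is at 2.33, 2.02 and 2.31, and the endothelial list reaches 5.59 at 7 weeks. Markers of other cell types are also high at 7 weeks, so the pan-reactive value there cannot be assigned to astrocytes.

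Across time, many genes called at 5.5 weeks were also at least 2-fold different at the other times. Of 126 genes that rose at 5.5 weeks and were measured at 5 weeks, 73 were at least 2-fold higher there (11.1 expected by chance overlap) and 12 at least 2-fold lower. Of 46 that fell, 30 were at least 2-fold lower at 5 weeks (5.6 expected). At 7 weeks the counts were 79 of 138 higher (12.6 expected) and 25 of 50 lower (2.8 expected). Of the 173 genes that rose at 5.5 weeks, those low in mock were measured at 5 or 7 weeks only if high after cuprizone. This raises the shares of 73 of 126 and 79 of 138, and the expected numbers do not allow for it. Gfap, Vim, Serping1, Gbp2, S1pr3 and A2m were higher at all 3 times, while C4b was at 0.25 at 5 weeks, 2.51 at 5.5 weeks and 3.14 at 7 weeks. Ttr was lower at 5 weeks and higher at both later times. Across genes, which are not independent replicates, log2 ratios had Pearson r = 0.276 and Spearman rho = 0.158 between 5 and 5.5 weeks, 0.421 and 0.402 between 5.5 and 7 weeks, and 0.067 and 0.016 between 5 and 7 weeks. Differences between time points were tested only in pooled fits, because 5 and 7 weeks have 1 library per group, and those at 5 weeks also differ in batch.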

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

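The tests on repeated libraries and on the 7-week library were chosen after the result was seen, as was the 7-week test that leaves out the noncoding class, added after the median of long noncoding RNAs came out at 0.049. The tests on membrane and cytosolic gene families at 5 weeks were written before their medians were seen. The genes with opposite signs were picked after their values were seen, so no independent test of their differences between time points exists, and differences of list medians were not tested.

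In 8 libraries a large share of the values repeat another library of the group, plus 1 to 10 counts, in data that the comparisons do not use. The percent of genes lying 1 to 10 counts above was 66.0 in 5-week cuprizone 2, 67.9 in 5-week cuprizone 3, 46.6 in 5-week mock 1, 96.2 in 5.5-week mock 2, 74.4 in 7-week mock 1, 85.8 in 7-week mock 2, 68.7 in 7-week cuprizone 1 and 87.2 in 7-week cuprizone 3. Sequencing the same RNA library again is argued against, since at least 46.8% of genes lay within 10 counts where sampling allows at most 15.6%. Counting the same reads again is argued against too, since at most 0.193% of genes were equal in any of the 8 and the library it repeats, and 6.848% at most between 2 repeats of 1 library. No biological explanation was tested, and the cause stays open.

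In the 7-week cuprizone library, microglial, vascular, mitochondrial and some noncoding RNAs were far higher than in mock. More microglia alone is argued against by medians of at least 2.878 in endothelial, pericyte and mitochondrial classes, and genomic DNA as the whole source by a median gain of 37.6 CPM in microglial markers against at most 1.413 CPM in any of 1736 olfactory and vomeronasal receptor genes, though their total of 96.3 CPM against 14.8 to 25.9 in the other 8 libraries leaves a smaller part open. RNA from outside the tagged ribosomes stays open: long noncoding RNAs went both ways, with a median of 0.049 and 28 of 103 at least 2-fold higher, which decides nothing, while their share was 1.01% against 0.262% to 0.334%. With that class left out the lowest median was 2.878, and such carry-over cannot be told apart from cuprizone, since 1 library stands for each group. A response of the tissue to cuprizone may account for part of it and stays open, untested.

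In the 5-week cuprizone library, transcripts of membrane and secreted proteins were lower. A smaller share of membrane-bound ribosomes in that library stays open: the family medians differed by −0.993, which measures the pattern itself and cannot be told apart from an effect of cuprizone in 1 library per group, while at 5.5 weeks they were 0.11 and −0.01 and at 7 weeks 0.21 and −0.35. Loss of oligodendrocyte RNA alone is argued against, since neuronal receptor families lay at −1.321 relative to the cytosolic families.

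Genes called at 5.5 weeks with the opposite sign of at least 2-fold at another time were marked for a closer look. The fit of the 9 libraries called the difference for all 14 gene and time pairs, which adds no support, since the pairs were picked for that difference and lone libraries were assumed to vary like the 5.5-week groups. At 5 weeks it also holds the difference in batch. At 5 weeks they were Gsn at −1.33, Ugt8a at −1.08, Mag at −1.51, Aplp2 at −1.93, Lgals3bp at −1.22, Ifi47 at −1.07, Serinc5 at −1.86, Nr4a1 at −1.37, Apod at −1.40, H2-D1 at −1.04, Mog at −2.48 and Ttr at −3.06, all of which rose at 5.5 weeks. At 7 weeks they were Heyl at 1.15, which fell by 1.16 at 5.5 weeks, and Nr4a1 at −2.42. For Nr4a1 the 7-week mock library was itself high, at 303.5 CPM against 86.5 and 96.7 CPM in the 5.5-week mock libraries. List medians of opposite sign at 5 and 7 weeks, each at least 1 in size on the log2 scale, were those of mitochondrial-genome genes, −1.89 and 2.88, and endothelial markers, −1.61 over 3 measured genes and 5.59 over 15.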

How the results depend on the processing

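The 9-library fit, the means of repeated libraries and the protein-coding count were chosen after the data were seen, the other alternatives before. At 5.5 weeks 173 genes rose and 63 fell, and none of these 236 changed sign under any alternative run. The counts moved by over 1.5 times to 381 and 162 with no filter on low counts, and to 100 and 36 with 1 CPM in 5 libraries, where 13163 genes were tested. A replicate block gave 481 and 269 with 1 residual degree of freedom, although the replicate numbers do not pair the samples. As deposited, 6 libraries of 5.5 weeks gave 314 higher, and all 17 libraries gave 614 higher and 175 lower, counting repeated libraries as replicates. Leaving out 1 library gave 49 to 189 higher and 16 to 85 lower, and where 1 mock library was left it was assumed to vary like the cuprizone libraries. With no filter the 5-week counts were 3323 higher and 4009 lower, and the 7-week counts 9028 and 1586, where low counts enter. Of 15 lists higher, 3 were called with an estimated correlation and 6 by directional fry, and of 5 lists lower, 0 and 1. The estimated correlation called 7 lists with no filter, where A2-type, antigen presentation, disease-associated microglial and cholesterol synthesis lists joined, 7 with the 6 libraries, where A2-type, cholesterol synthesis, immediate early and choroid plexus lists joined, and 8 with all 17. It called 2 with 1 CPM in 5 libraries, where too few complement genes were left for a test, and 0 with the block, the 9-library fit or any library left out. With the block the extracellular matrix, lipid transport and oligodendrocyte lists also lost their preset calls. The block had 18 preset calls in all against 20 in the main fit, so not every move was a loss. The cause of these moves was not tested except where given. Of 48 named genes called at 5.5 weeks, 15 were called with each library left out in turn and 11 lost their call under at least 1 other alternative. That tally leaves out genes named only for 5 or 7 weeks, such as Cd74, or only for an opposite sign, such as Gsn and Mag. It also counts a call as lost only where the alternative tested the gene. With 1 CPM in 5 libraries, 41 of 57 named genes kept their status, 6 lost their call and the rest were not tested. Of the 236 calls of the main fit, 136 were called with that filter. RLE, DESeq2, limma-voom, the 9-library fit and the means stayed within 1.5 times. With 1 library per group at 5 and 7 weeks, DESeq2, limma-voom, the block and leave-one-out were not run there, and differences between times were tested only in the pooled fits. The planned fit of all 17 libraries counts repeated libraries as replicates. It called 10842 genes at 5 weeks and 14404 at 7 weeks. For 5.5 minus 5 weeks it called 7302, for 7 minus 5.5 weeks 9936 and for 7 minus 5 weeks 11213. The 9-library fit, which assumes that lone libraries vary like the 5.5-week groups, called 6719 genes at 5 weeks and 7980 at 7 weeks, and 4701 genes for 5.5 minus 5 weeks, 3485 for 7 minus 5.5 weeks and 6528 for 7 minus 5 weeks.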

Other observations

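Single genes of the cell cycle, growth factors and metal handling differed between the 2 libraries at 5 weeks. In the 5-week cuprizone library the mitotic ubiquitin-conjugating enzyme Ube2c was 30.8-fold higher (95% interval 11.7 to 114.6) and the ribonucleotide reductase subunit Rrm2 had a log2 ratio of 2.22. The growth factors Fgf2 and Bmp4 were at 2.69 and 1.98, while Bmp2 and Gas6 were at −2.91 and −1.52. The copper transporter Atp7a and the zinc exporter Slc30a1 were at −2.05 and −2.04.

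At 7 weeks the growth factor Igf1 was at 3.98, the Notch ligand Jag1 at 2.28, the iron exporter Slc40a1 at 3.54 and ceruloplasmin, Cp, at 3.01, while Bdnf was at −1.40 and the metallothionein Mt3 at −1.23. Chemokines and cytokines went both ways, with the chemokines Cxcl16 at 3.89 and Cxcl12 at 2.19 and the cytokine Il33 at −1.40. These values come from 1 library per group.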
